A study of Danio rerio with 17 samples.

How the data were processed

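Polyadenylated RNA of cells sorted from dissociated eye tissue of adult zebrafish was sequenced in 17 libraries, read from both fragment ends after a strand-specific preparation per the labels. The fish carry a sox10-driven RFP reporter, alone (Control) or with homozygous brca2 hg5 alleles (PreC, Cancer). Groups and replicate numbers come from the sample titles: Control_Low, PreC_Low and PreC_High with 3 libraries each, Cancer_Low and Cancer_High with 4 each. The labels do not say that replicates are separate animals, so p-values measure the spread between these samples. Tissue codes in the sample descriptions tie each High library of PreC and Cancer to a Low library of the same tissue. Ages are 4.5 to 5.0 months in Control and PreC and 7.5 to 10.4 months in Cancer (1 age is typed with the letter O and was read as 5.0).

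The deposited table holds counts per gene, as whole numbers for 31701 Ensembl gene IDs, and was used as it stands. The submitters' processing notes name FastQC, STAR, HTSeq, DESeq2 and the genome build danRer10. Versions, the role of each tool, the annotation release and the strand setting are not given in the sources used here, and how reads shared between paralogs were counted was not analysed here. Library totals are 58711787 to 87244522 counts, with 20041 to 24179 genes detected. Libraries with indexes 1 to 9 hold 632 to 2344 IDs with 3 to 20 counts and 60.9 to 77.8% even values among counts of 20 to 100. The Cancer libraries, indexes 10 to 17, hold 3361 to 4295 such IDs and 51.2 to 53.9% even values. Pearson correlations of log2 CPM between libraries of a group ran from 0.881 to 0.953, and no pair of libraries held the same values. Symbols came from a reference table for 26237 of the 31701 IDs. They are printed as listed there, some in the capitals of human genes, and 4014 IDs share a symbol with another ID, in which case the ID is printed at each mention.

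All 17 libraries entered 1 edgeR 4.0.16 quasi-likelihood fit (R 4.3.3, limma 3.58.1) with 5 groups, TMM factors, robust shrinkage (median prior degrees of freedom 4.82) and filterByExpr with minimums of 10 counts per library and 15 in total, which kept 23299 genes. The comparisons are PreC_Low with Control_Low, Cancer_Low with Control_Low, Cancer_Low with PreC_Low, PreC_High with PreC_Low, Cancer_High with Cancer_Low, Cancer_High with PreC_High, and the interaction, the High against Low difference in Cancer less that in PreC. Genes with a Benjamini-Hochberg adjusted p under 0.05 count as called. CPM are edgeR values on TMM-scaled totals, given as mean ± SD, and log2 fold changes are given ± SE.

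28 gene lists were tested per comparison with limma camera (preset correlation 0.01, two-sided, log2 CPM with a prior count of 2), again with an estimated correlation, and with fry. Those reported cover myelin, neural crest and Schwann lineage, melanophore and retinal pigment epithelium, iridophore and xanthophore, photoreceptor, inner retina, synapse, Müller glia, macrophage, neutrophil, T and NK cell, B cell, endothelial, pericyte, fibroblast, erythrocyte, skeletal muscle, epithelial and lens genes, and cell cycle, homologous recombination, interferon, inflammatory, antigen presentation, dissociation and immediate early, Ras-MAPK output and glycolysis and hypoxia genes. Skeletal muscle and lens genes passed in no comparison with all libraries. Of 742 list symbols, 296 matched a listed symbol exactly, 219 apart from capitals, 133 after the paralogue letter was dropped and 56 not at all, and 38 matched only IDs that an earlier symbol of the same list had matched. This matching rule was chosen after the symbols were seen.

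Groups, tests, lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, per comparison, the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 2, groups that do not overlap and a proper symbol, then up to 4 members with the smallest adjusted p of each list that passed or had at least 3 called members, and genes fixed by name, among them SOX10 and brca2. For the interaction it takes 4 each way, overlap allowed. The text names part of these genes, mainly those whose call was kept without any 1 library, and none with 0 counts in a whole group. Some genes, 1 gene list and part of the genotype are not reported here.

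Alternatives were RLE factors, no filter, a filter of CPM of at least 1 in at least 3 libraries, DESeq2 1.42.0, limma voom with duplicateCorrelation on the tissue (consensus 0.181), only the compared groups, the replicate as a block, and each library left out in turn. Chosen after the data were seen were a minimum mean count of 100, the library index (1 to 5 or 6 to 9) as a block, PreC_Low 3 and Cancer_Low 4 both left out, and, for gene lists, the tissue block and the fits without a library. High and Low residuals of the same tissue correlated across genes at 0.306, 0.312, 0.331 and 0.426 in Cancer, each higher than with any other tissue, and at 0.023, -0.009 and 0.075 in PreC.

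The method was tested on simulated data with changed genes. With a true log2 change of 2, 20.9% were recovered for PreC_Low with Control_Low, 19.4% for Cancer_Low with PreC_Low, 28.4% for PreC_High with PreC_Low and 49.3% for Cancer_High with Cancer_Low. With a change of 3 these were 54.6, 56.1, 53.0 and 62.1%. False calls were 6 of 56, 0 of 50, 0 of 54 and 3 of 78. Shifting the interferon list gave adjusted p = 2.13e-09 and called no other list, but correlated genes were not tested. Figures used matplotlib 3.10.9.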

Results

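RNA was counted in 17 libraries of sorted cells from eyes of zebrafish that carry an RFP reporter driven by sox10, a neural crest and glial transcription factor gene. Control_Low (n = 3) holds sox10-low cells of fish without the brca2 mutation. PreC_Low and PreC_High (n = 3 each) hold sox10-low and sox10-high cells of homozygous brca2 mutant fish labelled as pre-cancerous, and Cancer_Low and Cancer_High (n = 4 each) hold those of mutant fish with cancer. SOX10 (ENSDARG00000077467) followed the sort, with 12.04 ± 1.19 library-scaled counts (CPM, mean ± SD) in Control_Low, 18.1 ± 7.36 in PreC_Low, 137 ± 188 in Cancer_Low, 1490 ± 142 in PreC_High and 1026 ± 272 in Cancer_High. brca2 (ENSDARG00000079015) was transcribed in each group, at 6.53, 14.7, 18.03, 13.6 and 10.3 CPM, in the same group order. Counts per gene do not show base changes, so the genotypes rest on the labels. Fold changes are log2 ± SE, and p-values are edgeR quasi-likelihood values after Benjamini-Hochberg adjustment over 23299 genes.

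**Figure D1:**
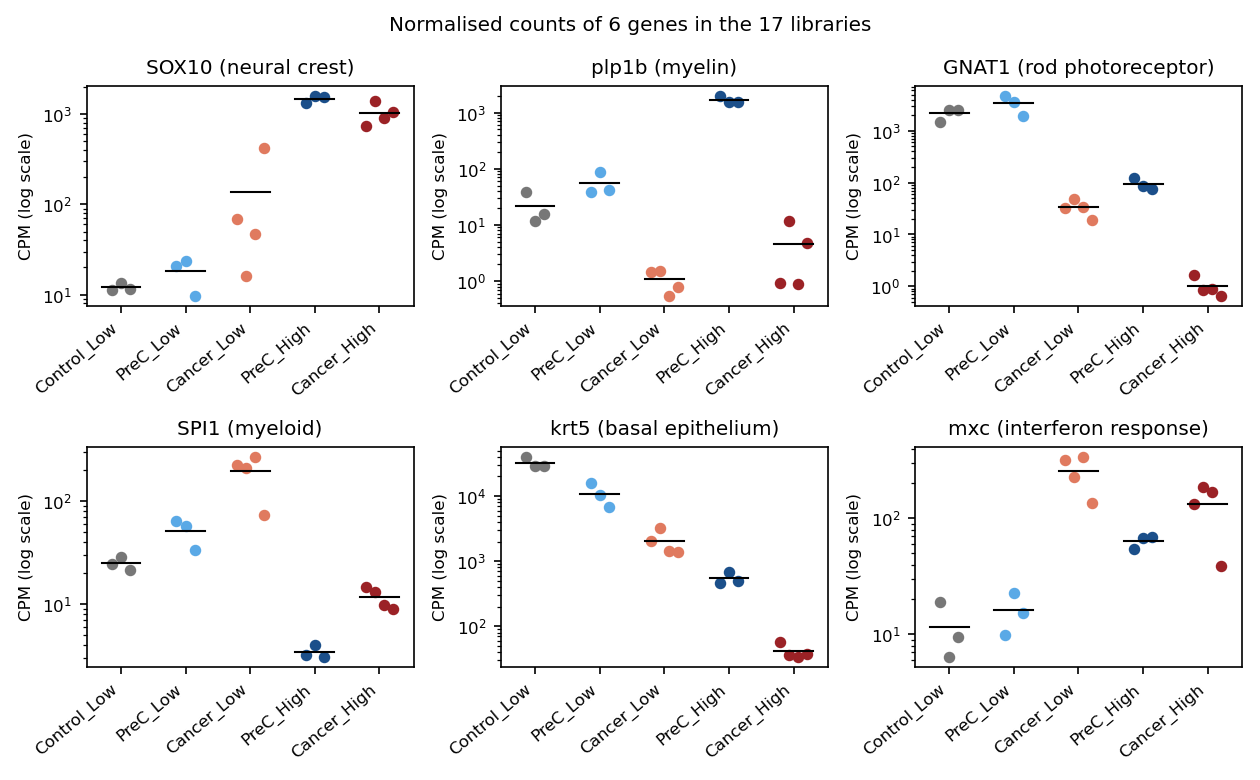
CPM on a log axis of SOX10, plp1b, GNAT1, SPI1, krt5 and mxc in each of the 17 libraries, by group, with a line at each group mean. SOX10 lies at 1490 ± 142 CPM in PreC_High and 1026 ± 272 CPM in Cancer_High, and 1 Cancer_Low library reaches 417.7 CPM.

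PreC_Low was compared with Control_Low for changes in mutant sox10-low cells before cancer. mhc2dab (ENSDARG00000079105), an MHC class II chain, rose from 4.33 ± 2.26 to 274 ± 107 CPM (log2 fold change 5.98 ± 0.68, adjusted p = 0.000391). ppp3cb (ENSDARG00000025106), a subunit of calcineurin, rose from 9.53 ± 0.383 to 356 ± 127 CPM (log2 fold change 5.22 ± 0.74, adjusted p = 0.00256). nlrc11 (ENSDARG00000068621), an NLR family gene, rose from 0.155 ± 0.166 to 62.4 ± 29.8 CPM (log2 fold change 8.61 ± 1.36, adjusted p = 0.00662). LOXL2 (ENSDARG00000044074), a lysyl oxidase, fell from 394 ± 49.6 to 15.2 ± 7.86 CPM (log2 fold change -4.70 ± 0.64, adjusted p = 0.0021). mhc2dab, nlrc11, LOXL2 and, below, tapbp.2, b2m and ifit16 also differed so from all controls in sox10-high mutant libraries. In all, 181 genes rose and 69 fell. Without PreC_Low 1 the rises were 311, and without PreC_Low 2 the falls were 29. Without PreC_Low 3 or Control_Low 1, 2 or 3, 34 to 58 rose and 16 to 29 fell.

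Antigen presentation and interferon response genes rose as lists in PreC_Low. Of antigen presentation genes, 4 of 19 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 2.27e-08, adjusted p = 0.185 with an estimated correlation). Its called members include the peptide loading gene tapbp.2 (ENSDARG00000045011) (log2 fold change 2.67 ± 0.49, adjusted p = 0.0176). The light chain of MHC class I, b2m (ENSDARG00000053136), stood at 1042 ± 98 against 450.0 ± 60 CPM (log2 fold change 1.21 ± 0.25, adjusted p = 0.0327). Of interferon response genes, 1 of 28 rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 5.60e-06, adjusted p = 0.487 with an estimated correlation). ifit16 (ENSDARG00000056976), an interferon-induced gene outside the list, rose (log2 fold change 5.06 ± 0.87, adjusted p = 0.0128), by log2 10.02 without Control_Low 1. Without PreC_Low 1, 2 or 3 the antigen genes that rose were 8, 2 and 1, and 1, 1 and 2 without Control_Low 1, 2 or 3. The interferon genes were 7 without PreC_Low 1 and 0 without PreC_Low 2, PreC_Low 3, Control_Low 1 or Control_Low 3. Calls of b2m ended without PreC_Low 2, PreC_Low 3 or any 1 control library (highest adjusted p = 0.134) and of tapbp.2 without PreC_Low 3, Control_Low 1 or Control_Low 2 (highest 0.106).

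T cell and cell cycle genes also rose as lists, and PreC_Low 3 stood apart in both. Of T and NK cell genes, 7 of 29 rose and 0 fell (18 and 0 adjusted over the list alone, camera adjusted p = 7.31e-12, adjusted p = 0.095 with an estimated correlation). CCR9 (ENSDARG00000055186), a chemokine receptor of developing T cells, rose from 68.8 ± 4.72 to 332 ± 55.5 CPM (log2 fold change 2.27 ± 0.43, adjusted p = 0.0219). il2rga (ENSDARG00000068858), the common cytokine receptor chain, rose from 9.08 ± 2.79 to 48.6 ± 9.04 CPM (log2 fold change 2.42 ± 0.48, adjusted p = 0.0293). Of cell cycle genes, 3 of 39 rose and 0 fell (25 and 0 adjusted over the list alone, camera adjusted p = 2.14e-09, adjusted p = 0.487 with an estimated correlation). The mitotic kinase gene plk1 (ENSDARG00000058471) stood at 21 ± 19.8 against 3.21 ± 0.984 CPM (log2 fold change 2.71 ± 0.56, adjusted p = 0.0327). The V(D)J recombinase genes RAG1 and RAG2, chosen after their values were seen, reached 1110 and 1020 CPM in PreC_Low 3 and at most 0.438 and 0.619 CPM in the other 9 Low libraries. Without PreC_Low 3 the T and NK cell list kept an adjusted p = 2.31e-11 and the cell cycle list 0.00143, with 0 members called in either. CCR9, il2rga and plk1 lost their calls there, as they did without any 1 control library (highest adjusted p = 0.117, 0.107 and 0.150). The log2 fold change of plk1 was 1.59 without PreC_Low 3. The T and NK cell genes that rose were 4 without PreC_Low 2 and 0 without Control_Low 1, 2 or 3. The cell cycle genes were 19 without PreC_Low 1, 6 without PreC_Low 2, 0 without Control_Low 1 or 2 and 1 without Control_Low 3.

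Other immune lists were higher and epithelial genes lower. Of B cell genes, 0 of 14 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.000188, adjusted p = 0.456 with an estimated correlation). Of macrophage and microglia genes, 2 of 28 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.00658, adjusted p = 0.78 with an estimated correlation), the call ending without PreC_Low 2 (adjusted p = 0.113). The genes that rose were 1 without PreC_Low 2 or 3 and 0 without Control_Low 1, 2 or 3. Of neutrophil genes, 0 of 16 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.0309, adjusted p = 0.78 with an estimated correlation), the call ending without PreC_Low 1, PreC_Low 2 or Control_Low 2 (highest adjusted p = 0.134). Of epithelial and keratin genes, 1 of 19 rose and 1 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.00215, adjusted p = 0.487 with an estimated correlation), with the direction down. krt92 (ENSDARG00000036834), a keratin, rose instead from 1.48 ± 0.488 to 78.3 ± 33.9 CPM (log2 fold change 5.73 ± 0.56, adjusted p = 6.35e-05). Of Müller glia and astroglia genes, 1 of 22 fell and 0 rose (3 and 0 adjusted over the list alone, camera adjusted p = 0.0159, adjusted p = 0.456 with an estimated correlation), again down. The prostaglandin D synthase gene ptgdsb.2 (ENSDARG00000071626) stood at 336 ± 93 against 1425 ± 150.1 CPM (log2 fold change -2.09 ± 0.31, adjusted p = 0.00469). Both calls ended without PreC_Low 3 (adjusted p = 0.152 and 0.160), and no epithelial gene fell without PreC_Low 2, PreC_Low 3 or any 1 control library. Homologous recombination genes (0 of 30 rose and 0 fell, 4 and 0 adjusted over the list alone, camera adjusted p = 0.000103, adjusted p = 0.501 with an estimated correlation) lost their call without PreC_Low 3 (adjusted p = 0.139), and 2 rose without PreC_Low 1. Ras-MAPK output genes (0 of 25 rose and 0 fell, 1 and 0 adjusted over the list alone, camera adjusted p = 0.0309, adjusted p = 0.487 with an estimated correlation, down) lost theirs without PreC_Low 3, Control_Low 1 or Control_Low 3 (highest adjusted p = 0.543), and 1 rose without PreC_Low 1 or 2. SOX10 and brca2 did not pass the test (log2 fold changes 0.59 ± 0.74 and 1.17 ± 0.41).

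No list of this comparison held with an estimated correlation, and fry called 2 of the 11, T and NK cell and antigen presentation genes. The count of 250 genes became 1497 by DESeq2, 783 by limma voom and 866 with only these groups in the fit. The share that rose, 72.4%, was 60.3% with RLE scaling, which moved the median log2 fold change of all genes from 0.094 to -0.023. It was 52.2% with only these groups in the fit, 42.2% with the replicate block (445 rises, 609 falls) and 36.8% by limma voom (288 and 495). That more genes rose than fell therefore depends on the fit. Fibroblast genes, not passing with all libraries, did so without PreC_Low 2 or Control_Low 1 (adjusted p = 0.00333 and 0.00998), as did photoreceptor genes (0.0372 and 0.0366).

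**Figure D2:**
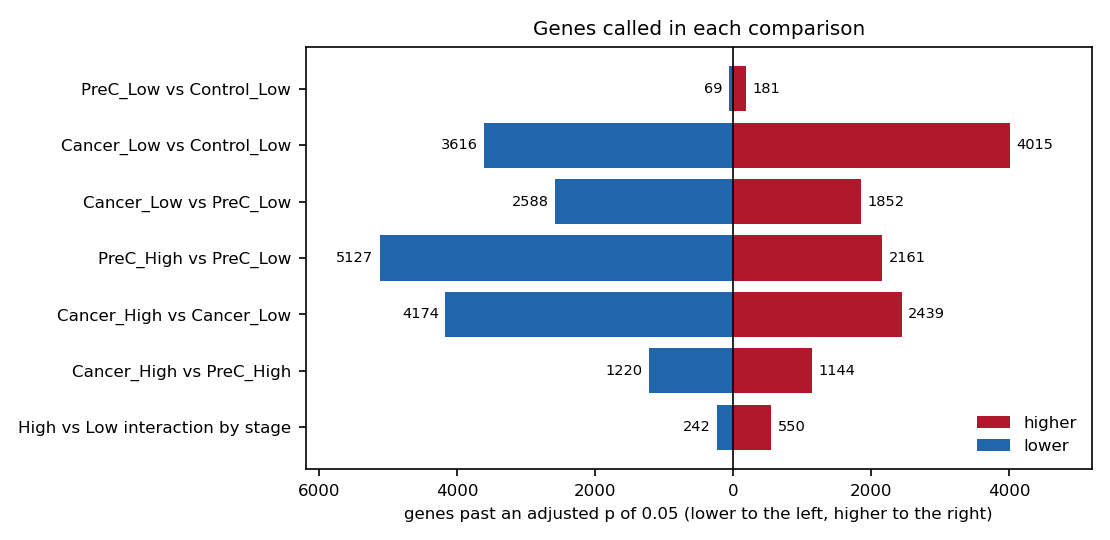
Bars from 0 give the number of genes higher and lower at an adjusted p under 0.05 in each comparison, out of 23299 tested. PreC_Low against Control_Low has 181 higher and 69 lower, and Cancer_Low against Control_Low 4015 and 3616.

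In cancer, the sox10-low fraction carried high interferon and myeloid and low retinal transcripts against Control_Low. cxcl11.3 (ENSDARG00000102514), an interferon-induced chemokine, rose from 0.695 ± 0.585 to 217 ± 130.3 CPM (log2 fold change 8.30 ± 0.88, adjusted p = 5.13e-06). SPI1 (ENSDARG00000000767), the myeloid transcription factor PU.1, rose from 24.9 ± 3.54 to 193 ± 82.8 CPM (log2 fold change 2.95 ± 0.40, adjusted p = 4.37e-05). GNAT1 (ENSDARG00000044199), the rod transducin, fell from 2181 ± 587 to 33.5 ± 11.8 CPM (log2 fold change -6.03 ± 0.44, adjusted p = 3.77e-07). krt5 (ENSDARG00000058371), a basal keratin, fell from 32470 ± 5811 to 2010 ± 845 CPM (log2 fold change -4.01 ± 0.35, adjusted p = 8.63e-07). In all, 4015 genes rose and 3616 fell, the rises being 2632 without Control_Low 3. Falls outnumbered rises without any 1 control library and by limma voom (4383 to 3992).

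Of interferon response genes, 27 of 28 rose and 0 fell (27 and 0 adjusted over the list alone, camera adjusted p = 7.33e-15, adjusted p = 0.0902 with an estimated correlation). Of antigen presentation genes, 17 of 19 rose and 0 fell (18 and 0 adjusted over the list alone, camera adjusted p = 4.95e-10, adjusted p = 0.0559 with an estimated correlation). The antiviral GTPase gene mxc (ENSDARG00000024789) reached 254 ± 91.7 against 11.7 ± 6.58 CPM (log2 fold change 4.45 ± 0.57, adjusted p = 2.96e-05). The immunoproteasome gene PSMB8 (ENSDARG00000001303) reached 258 ± 73.5 against 25.8 ± 0.442 CPM (log2 fold change 3.32 ± 0.41, adjusted p = 1.94e-05), and b2m 2227 ± 516 against 450.0 ± 60 CPM (log2 fold change 2.31 ± 0.25, adjusted p = 5.98e-06). Of inflammatory signalling genes, 19 of 34 rose and 4 fell (23 and 4 adjusted over the list alone, camera adjusted p = 3.69e-05, adjusted p = 0.285 with an estimated correlation). ACOD1 (ENSDARG00000069844), which makes itaconate in activated macrophages, is among its largest rises (log2 fold change 9.11 ± 1.44, adjusted p = 0.000175).

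Immune cell genes rose on the macrophage, neutrophil, T and NK cell and B cell lists. Of macrophage and microglia genes, 20 of 28 rose and 2 fell (22 and 2 adjusted over the list alone, camera adjusted p = 5.46e-07, adjusted p = 0.295 with an estimated correlation). Among them are the complement gene c1qa (ENSDARG00000044613) (log2 fold change 3.73 ± 0.54, adjusted p = 8.31e-05) and IRF8 (ENSDARG00000056407) (log2 fold change 3.40 ± 0.50, adjusted p = 0.000104), a myeloid transcription factor. Of neutrophil genes, 12 of 16 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 7.37e-05, adjusted p = 0.295 with an estimated correlation). The granule proteoglycan gene srgn (ENSDARG00000077069) stood at 857 ± 404 against 77.1 ± 11.1 CPM (log2 fold change 3.47 ± 0.43, adjusted p = 2.03e-05). The neutrophil genes that rose were 8 without Control_Low 2. Of T and NK cell genes, 9 of 29 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.001, adjusted p = 0.295 with an estimated correlation). The cytotoxic granule gene nkl.2 (ENSDARG00000058673) had the largest rise of those named (log2 fold change 7.02 ± 1.09, adjusted p = 0.000155). Of B cell genes, 8 of 14 rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 0.00838, adjusted p = 0.343 with an estimated correlation). The count of B cell genes was 5 without Control_Low 1, 2 or 3 or Cancer_Low 3.

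Of cell cycle genes, 31 of 39 rose and 0 fell (32 and 0 adjusted over the list alone, camera adjusted p = 2.92e-10, adjusted p = 0.295 with an estimated correlation). Examples are thymidylate synthase, TYMS (ENSDARG00000042894) (log2 fold change 3.88 ± 0.54, adjusted p = 6.01e-05), and plk1 (log2 fold change 3.56 ± 0.56, adjusted p = 0.000181). Of homologous recombination genes, 9 of 30 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 7.74e-05, adjusted p = 0.343 with an estimated correlation), including RAD50 (ENSDARG00000038917) (log2 fold change 2.06 ± 0.36, adjusted p = 0.000433), part of the complex that processes double-strand breaks. brca2 rose from 6.53 ± 0.738 to 18 ± 6.46 CPM (log2 fold change 1.47 ± 0.39, adjusted p = 0.00881).

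Retinal genes fell. Of photoreceptor genes, 30 of 30 fell and 0 rose (30 and 0 adjusted over the list alone, camera adjusted p = 5.57e-27, adjusted p = 0.0126 with an estimated correlation). Of synapse genes, 17 of 33 fell and 0 rose (17 and 0 adjusted over the list alone, camera adjusted p = 2.43e-07, adjusted p = 0.0126 with an estimated correlation). Of Müller glia and astroglia genes, 13 of 22 fell and 0 rose (13 and 0 adjusted over the list alone, camera adjusted p = 6.03e-08, adjusted p = 0.0126 with an estimated correlation). The apolipoprotein gene apoeb (ENSDARG00000040295) fell from 6677 ± 860.0 to 426 ± 19.8 CPM (log2 fold change -3.97 ± 0.33, adjusted p = 6.27e-07), and the synaptophysin gene sypb (ENSDARG00000002230) by log2 -4.86 ± 0.48 (adjusted p = 2.49e-06). Of inner retina and other neuronal genes, 19 of 37 fell and 1 rose (20 and 1 adjusted over the list alone, camera adjusted p = 2.45e-07, adjusted p = 0.0785 with an estimated correlation). Of epithelial and keratin genes, 12 of 19 fell and 4 rose (12 and 4 adjusted over the list alone, camera adjusted p = 0.000948, adjusted p = 0.295 with an estimated correlation). krt18b (ENSDARG00000028618), a keratin of simple epithelia, rose and stood at 1711 ± 1097 against 128 ± 33.9 CPM. Of endothelial genes, 6 of 22 fell and 0 rose (6 and 0 adjusted over the list alone, camera adjusted p = 0.0243, adjusted p = 0.411 with an estimated correlation). Without Control_Low 2, 2 endothelial genes fell and the call ended (adjusted p = 0.0906), as it did without Cancer_Low 4 (0.0842). Of oligodendrocyte and myelin genes, 8 of 19 fell and 3 rose (10 and 4 adjusted over the list alone, camera adjusted p = 0.0491, adjusted p = 0.388 with an estimated correlation). plp1b (ENSDARG00000011929), a myelin proteolipid, was lower (log2 fold change -4.34 ± 0.76, adjusted p = 0.000415). The list lost its call without Control_Low 1, Control_Low 3, Cancer_Low 3 or Cancer_Low 4 (adjusted p = 0.0886, 0.0566, 0.0537 and 0.0866), with 5 genes falling without each of the first 3, and with RLE scaling (0.0504).

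Iridophore and xanthophore genes and SOX10 were higher, and 1 library stood apart in SOX10. Of iridophore and xanthophore genes, 8 of 19 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.0227, adjusted p = 0.365 with an estimated correlation). Melanophore and retinal pigment epithelium genes did not pass as a list (3 of 20 rose and 3 fell, 4 and 3 adjusted over the list alone, camera adjusted p = 0.756). The transcription factor gene TFEC (ENSDARG00000098745) stood at 115 ± 73.4 against 7.25 ± 1.49 CPM (log2 fold change 3.99 ± 0.45, adjusted p = 1.01e-05). SOX10 rose by log2 3.51 ± 0.80 (adjusted p = 0.00297), and by 1.87 without Cancer_Low 4 (adjusted p = 0.00345), whose SOX10 level was 417.7 CPM against 16.04 to 69.1 CPM in the other 3. Glycolysis and hypoxia genes (18 of 41 rose and 6 fell, 20 and 8 adjusted over the list alone, camera adjusted p = 0.0613) did not pass as a list, except without Cancer_Low 3 (adjusted p = 0.0280). Fibroblast and extracellular matrix genes (9 of 37 rose and 6 fell, 10 and 8 adjusted over the list alone, camera adjusted p = 0.926) and neural crest genes (4 of 26 rose and 4 fell, 4 and 4 adjusted over the list alone, camera adjusted p = 0.796) did not pass either.

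In this and the other comparisons of stages, the Cancer libraries carry indexes 10 to 17 and come from fish aged 7.5 to 10.4 months, the others indexes 1 to 9 and ages of 4.5 to 5.0 months. Stage therefore cannot be told apart from library series or age. Mitochondrial genes took 6.84 to 10.9% of counts in Control_Low, 7.15 to 16.7% in PreC_Low and 2.87 to 6.22% in the Cancer and PreC_High libraries.

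Against PreC_Low, the sox10-low fraction of cancer showed the same lists of interferon, myeloid and inflammatory genes higher and of photoreceptor and neuronal genes lower. GNAT1 fell from 3420 ± 1394 to 33.5 ± 11.8 CPM (log2 fold change -6.67 ± 0.45, adjusted p = 3.15e-07). SAA2 (ENSDARG00000045999), an acute phase gene, rose from 7.48 ± 2.04 to 328 ± 244 CPM (log2 fold change 5.45 ± 0.76, adjusted p = 0.000101). mxc rose from 16.1 ± 6.52 to 254 ± 91.7 CPM (log2 fold change 3.98 ± 0.56, adjusted p = 0.000107). In all, 1852 genes rose and 2588 fell, the rises being 1020 without PreC_Low 1 and 1012 without PreC_Low 2.

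Of interferon response genes, 23 of 28 rose and 0 fell (27 and 0 adjusted over the list alone, camera adjusted p = 5.60e-14, adjusted p = 0.126 with an estimated correlation). Of antigen presentation genes, 8 of 19 rose and 0 fell (17 and 0 adjusted over the list alone, camera adjusted p = 1.63e-06, adjusted p = 0.135 with an estimated correlation). b2m stood at 2227 ± 516 against 1042 ± 98 CPM (adjusted p = 0.00365). Of inflammatory signalling genes, 15 of 34 rose and 1 fell (22 and 2 adjusted over the list alone, camera adjusted p = 5.72e-06, adjusted p = 0.204 with an estimated correlation). ACOD1 rose (log2 fold change 6.82 ± 1.29, adjusted p = 0.00142), as did cxcl8a (ENSDARG00000104795), a neutrophil chemokine (log2 fold change 2.59 ± 0.55, adjusted p = 0.00323). Of macrophage and microglia genes, 15 of 28 rose and 1 fell (19 and 1 adjusted over the list alone, camera adjusted p = 4.07e-06, adjusted p = 0.336 with an estimated correlation). Of neutrophil genes, 8 of 16 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.00029, adjusted p = 0.329 with an estimated correlation). SPI1 rose from 51.3 ± 15.9 to 193 ± 82.8 CPM (log2 fold change 1.91 ± 0.38, adjusted p = 0.00187) and the NADPH oxidase gene cyba (ENSDARG00000018283) from 44.9 ± 3.66 to 264 ± 136 CPM (log2 fold change 2.56 ± 0.43, adjusted p = 0.000534). T and NK cell genes did not pass as a list (6 of 29 fell and 1 rose, 7 and 1 adjusted over the list alone, camera adjusted p = 0.346). Members went both ways: nkl.2 rose (log2 fold change 5.88 ± 1.03, adjusted p = 0.000778), whereas RUNX3 (ENSDARG00000052826), a transcription factor of cytotoxic T cells, fell (log2 fold change -2.16 ± 0.48, adjusted p = 0.00429). Without PreC_Low 3, which holds the RAG1 and RAG2 transcripts, 10 inflammatory genes rose.

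Of glycolysis and hypoxia genes, 16 of 41 rose and 6 fell (18 and 7 adjusted over the list alone, camera adjusted p = 0.00946, adjusted p = 0.329 with an estimated correlation). Lactate dehydrogenase, LDHA (ENSDARG00000101251), rose (log2 fold change 2.97 ± 0.45, adjusted p = 0.000208), as did the angiogenic factor VEGFA (ENSDARG00000034700) (log2 fold change 3.50 ± 0.53, adjusted p = 0.000217). Of fibroblast and extracellular matrix genes, 8 of 37 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.156), not passing as a list unless PreC_Low 2 or Cancer_Low 2 was left out (adjusted p = 0.0156 and 0.0103). Even so, the membrane metalloproteinase gene MMP14 (ENSDARG00000008388) rose from 49.8 ± 11.1 to 285 ± 134 CPM (log2 fold change 2.52 ± 0.37, adjusted p = 0.000179). The chaperone gene HSPA5 (ENSDARG00000103846), from the dissociation and immediate early list, rose from 416 ± 162 to 2371 ± 653 CPM (log2 fold change 2.51 ± 0.39, adjusted p = 0.000295). Of iridophore and xanthophore genes, 8 of 19 rose and 0 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.0195, adjusted p = 0.394 with an estimated correlation). Melanophore and retinal pigment epithelium genes did not pass (3 of 20 rose and 3 fell, 4 and 3 adjusted over the list alone, camera adjusted p = 0.367). Homologous recombination genes did not either (1 of 30 rose and 0 fell, 0 and 0 adjusted over the list alone, camera adjusted p = 0.0504), but did with RLE scaling (adjusted p = 0.0390) and without PreC_Low 3 (0.000485, 9 rising), Cancer_Low 1 (0.0290) or Cancer_Low 4 (0.0413). Of cell cycle genes, 1 of 39 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 3.58e-05, adjusted p = 0.558 with an estimated correlation). The 1 call, TYMS, became 26 without PreC_Low 3, 2 without Cancer_Low 4 and 0 without PreC_Low 1, PreC_Low 2, Cancer_Low 1 or Cancer_Low 3. SOX10 rose (log2 fold change 2.93 ± 0.77, adjusted p = 0.0135), with log2 1.28 without Cancer_Low 4 (adjusted p = 0.0419) and no call without PreC_Low 3 (0.0501).

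Of photoreceptor genes, 28 of 30 fell and 0 rose (30 and 0 adjusted over the list alone, camera adjusted p = 1.61e-34, adjusted p = 0.00595 with an estimated correlation). Of synapse genes, 14 of 33 fell and 0 rose (18 and 0 adjusted over the list alone, camera adjusted p = 3.57e-08, adjusted p = 0.00874 with an estimated correlation). Of inner retina and other neuronal genes, 20 of 37 fell and 1 rose (22 and 1 adjusted over the list alone, camera adjusted p = 3.00e-10, adjusted p = 0.0295 with an estimated correlation). Of Müller glia and astroglia genes, 11 of 22 fell and 0 rose (11 and 0 adjusted over the list alone, camera adjusted p = 6.95e-08, adjusted p = 0.013 with an estimated correlation). The glial filament gene GFAP (ENSDARG00000025301) fell from 41 ± 5.18 to 4.61 ± 0.451 CPM (log2 fold change -3.16 ± 0.32, adjusted p = 5.84e-06). Without PreC_Low 1, 12 inner retina genes fell. Of oligodendrocyte and myelin genes, 8 of 19 fell and 2 rose (8 and 3 adjusted over the list alone, camera adjusted p = 0.00946, adjusted p = 0.329 with an estimated correlation), and 5 fell without PreC_Low 2. Of epithelial and keratin genes, 9 of 19 fell and 3 rose (11 and 3 adjusted over the list alone, camera adjusted p = 0.00648, adjusted p = 0.394 with an estimated correlation), with krt5 at log2 fold change -2.44 ± 0.33, adjusted p = 7.93e-05. Of endothelial genes, 3 of 22 fell and 0 rose (2 and 0 adjusted over the list alone, camera adjusted p = 0.0228, adjusted p = 0.512 with an estimated correlation). That call ended without PreC_Low 2 or Cancer_Low 4 (adjusted p = 0.128 and 0.104), and 1 fell without PreC_Low 1, PreC_Low 2, Cancer_Low 2 or Cancer_Low 3.

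PreC_Low and Cancer_Low shared changes against Control_Low. Of the genes called in both, 167 rose, 62 fell and 0 went opposite ways, where independent calls would share 31.2 and 10.7. Both comparisons use the same 3 controls, too few to split, so part of the excess may come from them. Across genes, not independent replicates, fold changes correlated at r = 0.616 (covariance 2.66). Groups simulated without change against the same controls gave means of 0.545 and 0.450 in 20 simulations. The correlation was 0.462 without PreC_Low 3 (covariance 2.21) and 0.476 without PreC_Low 3 and Cancer_Low 4, neither fit simulated. The shared calls were 77 without PreC_Low 3, 48, 79 and 70 without Control_Low 1, 2 or 3, and 361 without PreC_Low 1, against 229 with all. Without PreC_Low 2, 26 fell in both. By limma voom 217 rose and 455 fell in both. mhc2dab, b2m, nlrc11 and ifit16 were higher in both, and ptgdsb.2, krt5 and LOXL2 lower. Each differed so from all controls in sox10-high cells too, as a strain variant might.

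**Figure D3:**
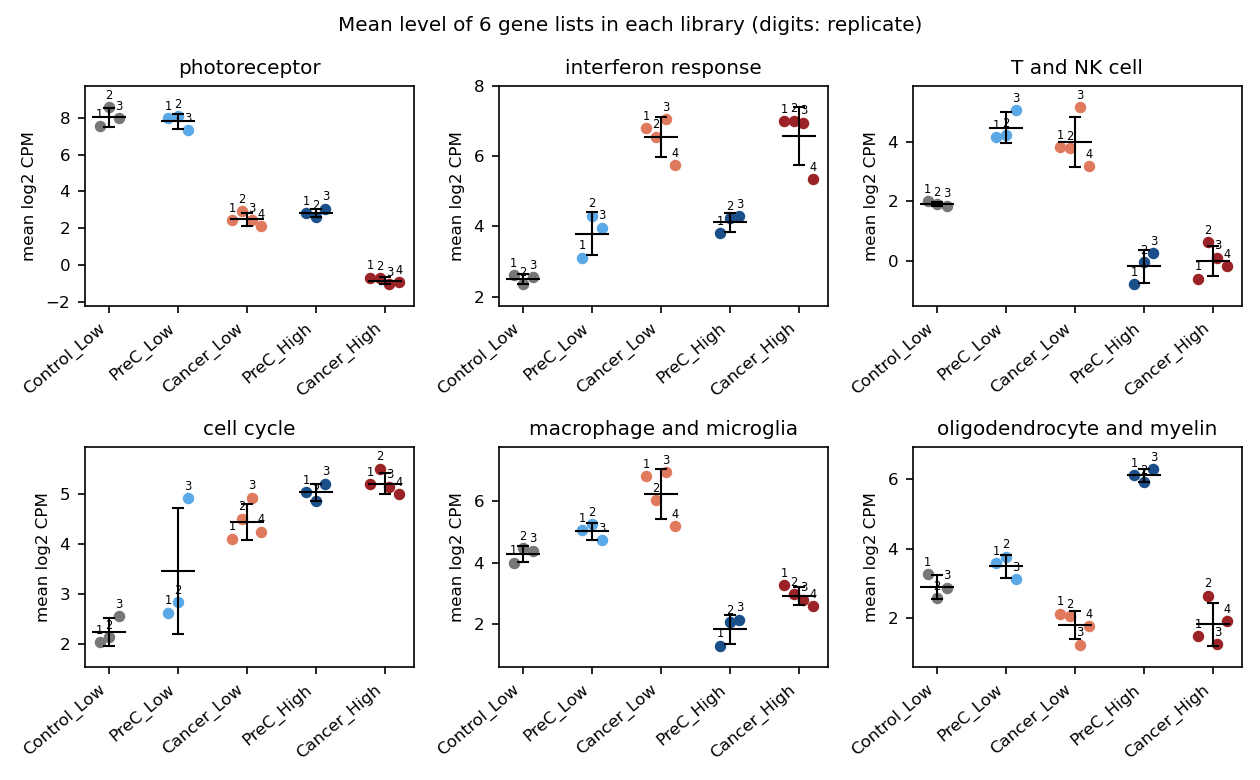
Mean log2 CPM of the genes of 6 lists in each library (digits give the replicate) by group, with bars at the group mean ± SD. The myelin list stands at 6.10 ± 0.19 in PreC_High and 1.83 ± 0.62 in Cancer_High, and the interferon list at 6.55 ± 0.57 in Cancer_Low and 6.58 ± 0.82 in Cancer_High.

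Between the sorted fractions of pre-cancerous eyes, sox10-high cells carried myelin, neural crest and pigment cell transcripts and sox10-low cells those of immune, epithelial, vascular and retinal cells. SOX10 was higher in PreC_High (log2 fold change 6.37 ± 0.93, adjusted p = 0.000114), as was the glial calcium-binding gene S100B (ENSDARG00000057598) (log2 fold change 6.68 ± 1.29, adjusted p = 0.000972). plp1b stood at 1686 ± 245 against 56.2 ± 26.8 CPM (log2 fold change 4.91 ± 0.87, adjusted p = 0.000535). GPNMB (ENSDARG00000062688), a pigment cell glycoprotein gene, stood at 1594 ± 329.5 against 16.8 ± 5.87 CPM (log2 fold change 6.56 ± 1.04, adjusted p = 0.000216). ptprc (ENSDARG00000071437), the leukocyte antigen CD45, was lower at 20.3 ± 6.34 against 343 ± 53 CPM (log2 fold change -4.08 ± 0.42, adjusted p = 8.55e-06). In all, 2161 genes were higher and 5127 lower, the former being 1332 without PreC_Low 1 and 1345 without PreC_Low 2.

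Of oligodendrocyte and myelin genes, 11 of 19 rose and 2 fell (13 and 2 adjusted over the list alone, camera adjusted p = 9.53e-06, adjusted p = 0.129 with an estimated correlation). Müller glia and astroglia genes did not pass as a list (11 of 22 fell and 3 rose, 11 and 4 adjusted over the list alone, camera adjusted p = 0.131). Of neural crest and Schwann lineage genes, 7 of 26 rose and 4 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.0173, adjusted p = 0.228 with an estimated correlation), a call that ended without PreC_Low 3 (adjusted p = 0.132). Of melanophore and retinal pigment epithelium genes, 8 of 20 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.000699, adjusted p = 0.164 with an estimated correlation). Of iridophore and xanthophore genes, 10 of 19 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.000209, adjusted p = 0.164 with an estimated correlation), with TFEC (log2 fold change 4.72 ± 0.48, adjusted p = 7.75e-06) on both lists. Of cell cycle genes, 9 of 39 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 5.59e-09, adjusted p = 0.27 with an estimated correlation). With tissue as a block the cell cycle genes that rose were 30 (camera adjusted p = 5.22e-09). They were 34 without PreC_Low 3, and 5, 2 and 3 without PreC_High 1, PreC_Low 1 or PreC_Low 2. Of homologous recombination genes, 4 of 30 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.000704, adjusted p = 0.364 with an estimated correlation), 12 without PreC_Low 3 and 1 without PreC_High 2, PreC_High 3, PreC_Low 1 or PreC_Low 2.

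Of photoreceptor genes, 28 of 30 fell and 0 rose (28 and 0 adjusted over the list alone, camera adjusted p = 1.04e-18, adjusted p = 0.0664 with an estimated correlation). Of inner retina genes, 22 of 37 fell and 2 rose (26 and 3 adjusted over the list alone, camera adjusted p = 7.22e-05, adjusted p = 0.164 with an estimated correlation). Of synapse genes, 14 of 33 fell and 0 rose (14 and 0 adjusted over the list alone, camera adjusted p = 0.00097, adjusted p = 0.129 with an estimated correlation). Of macrophage and microglia genes, 22 of 28 fell and 0 rose (23 and 0 adjusted over the list alone, camera adjusted p = 2.44e-09, adjusted p = 0.164 with an estimated correlation). Of neutrophil genes, 13 of 16 fell and 2 rose (13 and 2 adjusted over the list alone, camera adjusted p = 0.000209, adjusted p = 0.228 with an estimated correlation). Of T and NK cell genes, 24 of 29 fell and 0 rose (28 and 0 adjusted over the list alone, camera adjusted p = 2.44e-09, adjusted p = 0.113 with an estimated correlation). Of B cell genes, 9 of 14 fell and 0 rose (10 and 1 adjusted over the list alone, camera adjusted p = 0.000665, adjusted p = 0.188 with an estimated correlation). SPI1 stood at 3.42 ± 0.53 against 51.3 ± 15.9 CPM (log2 fold change -3.90 ± 0.43, adjusted p = 1.19e-05). Of endothelial genes, 17 of 22 fell and 0 rose (18 and 0 adjusted over the list alone, camera adjusted p = 3.77e-06, adjusted p = 0.164 with an estimated correlation). Of epithelial and keratin genes, 15 of 19 fell and 3 rose (15 and 3 adjusted over the list alone, camera adjusted p = 7.22e-05, adjusted p = 0.172 with an estimated correlation). Of fibroblast and extracellular matrix genes, 18 of 37 fell and 5 rose (18 and 6 adjusted over the list alone, camera adjusted p = 0.0149, adjusted p = 0.516 with an estimated correlation). Of glycolysis and hypoxia genes, 19 of 41 fell and 2 rose (21 and 3 adjusted over the list alone, camera adjusted p = 0.000821, adjusted p = 0.164 with an estimated correlation). Of erythrocyte genes, 8 of 12 fell and 0 rose (8 and 0 adjusted over the list alone, camera adjusted p = 0.0154, adjusted p = 0.228 with an estimated correlation). Of inflammatory genes, 11 of 34 fell and 4 rose (13 and 5 adjusted over the list alone, camera adjusted p = 0.0396, adjusted p = 0.449 with an estimated correlation). Ras-MAPK output genes (10 of 25 rose and 5 fell, 11 and 6 adjusted over the list alone, camera adjusted p = 0.047, adjusted p = 0.321 with an estimated correlation) rose in part, with the phosphatase gene DUSP4 (ENSDARG00000044688) at log2 fold change 2.73 ± 0.39, adjusted p = 0.000103. Calls ended without PreC_Low 2 for fibroblast, erythrocyte and inflammatory genes (adjusted p = 0.0634, 0.0527 and 0.0662) and without PreC_High 3 for inflammatory genes (0.0636). Ras-MAPK genes lost theirs without PreC_High 1 or PreC_Low 3 (0.108 and 0.207), with tissue as a block (0.0788) and with RLE scaling (0.0542). The erythrocyte genes that fell were 4 without PreC_High 2 and 5 without PreC_Low 1 or 2. Interferon response genes did not pass as a list (3 of 28 rose and 1 fell, 3 and 1 adjusted over the list alone, camera adjusted p = 0.169), except without PreC_Low 2 (adjusted p = 0.0263). No list of this comparison held with an estimated correlation.

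In cancer, the sox10-high fraction again held higher SOX10 and pigment cell genes and lower immune, epithelial, stromal and retinal genes than the sox10-low fraction. SOX10 was higher (log2 fold change 2.90 ± 0.69, adjusted p = 0.00499), and its log2 fold change was 4.55 without Cancer_Low 4 (adjusted p = 2.69e-06). krt5 stood at 41.2 ± 11 against 2010 ± 845 CPM (log2 fold change -5.61 ± 0.37, adjusted p = 2.15e-07), and SPI1 at 11.6 ± 2.63 against 193 ± 82.8 CPM (log2 fold change -4.06 ± 0.37, adjusted p = 1.91e-06). The fibronectin gene FN1 (ENSDARG00000019815) stood at 13.9 ± 7.25 against 507 ± 358 CPM (log2 fold change -5.19 ± 0.52, adjusted p = 3.57e-06). In all, 2439 genes were higher and 4174 lower, the former being 1284, 1318 and 1514 without Cancer_Low 1, 2 or 3.

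Of melanophore and retinal pigment epithelium genes, 7 of 20 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.00164, adjusted p = 0.166 with an estimated correlation). Of iridophore and xanthophore genes, 10 of 19 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 0.00191, adjusted p = 0.194 with an estimated correlation). GPR143 (ENSDARG00000034572), a melanosome receptor gene, stood at 109 ± 56.7 against 7.82 ± 8.31 CPM (log2 fold change 3.80 ± 0.88, adjusted p = 0.00415), and ATIC (ENSDARG00000016706), an enzyme of purine synthesis, was higher (log2 fold change 2.13 ± 0.47, adjusted p = 0.00316). The iridophore genes that rose were 4 without Cancer_Low 1 and 6 without Cancer_Low 3. Of cell cycle genes, 4 of 39 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.000182, adjusted p = 0.533 with an estimated correlation), and 7 rose with tissue as a block. Without 1 library the 4 became 1 (Cancer_High 2 or Cancer_Low 2), 2 (Cancer_High 3 or Cancer_Low 4) or 0 (Cancer_Low 1). Homologous recombination genes did not pass as a list (3 of 30 rose and 1 fell, 3 and 1 adjusted over the list alone, camera adjusted p = 0.0571), but did with tissue as a block (adjusted p = 0.0464) and without Cancer_High 3, Cancer_High 4 or Cancer_Low 3 (0.0434, 0.0286 and 0.0137). Myelin genes (4 of 19 rose and 3 fell, 4 and 3 adjusted over the list alone, camera adjusted p = 0.666) and neural crest genes (7 of 26 rose and 6 fell, 9 and 6 adjusted over the list alone, camera adjusted p = 0.519) did not pass as lists. Interferon response genes did not either (2 of 28 rose and 2 fell, 2 and 2 adjusted over the list alone, camera adjusted p = 0.497), except without Cancer_High 4 (adjusted p = 0.0478). S100B was higher (log2 fold change 4.67 ± 1.01, adjusted p = 0.00268).

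Of macrophage and microglia genes, 24 of 28 fell and 0 rose (25 and 0 adjusted over the list alone, camera adjusted p = 1.29e-15, adjusted p = 0.135 with an estimated correlation). Of neutrophil genes, 14 of 16 fell and 1 rose (14 and 1 adjusted over the list alone, camera adjusted p = 4.88e-07, adjusted p = 0.166 with an estimated correlation). Of T and NK cell genes, 27 of 29 fell and 0 rose (27 and 0 adjusted over the list alone, camera adjusted p = 2.88e-12, adjusted p = 0.0554 with an estimated correlation). Of B cell genes, 11 of 14 fell and 0 rose (12 and 0 adjusted over the list alone, camera adjusted p = 1.67e-05, adjusted p = 0.166 with an estimated correlation). Without Cancer_High 1, Cancer_High 3 or Cancer_Low 3, 7 B cell genes fell. Of inflammatory genes, 22 of 34 fell and 1 rose (22 and 2 adjusted over the list alone, camera adjusted p = 2.40e-06, adjusted p = 0.166 with an estimated correlation). Of fibroblast and extracellular matrix genes, 23 of 37 fell and 0 rose (25 and 1 adjusted over the list alone, camera adjusted p = 4.92e-08, adjusted p = 0.194 with an estimated correlation). Of epithelial and keratin genes, 13 of 19 fell and 2 rose (14 and 2 adjusted over the list alone, camera adjusted p = 5.31e-08, adjusted p = 0.135 with an estimated correlation). Of endothelial genes, 12 of 22 fell and 0 rose (14 and 0 adjusted over the list alone, camera adjusted p = 1.91e-05, adjusted p = 0.166 with an estimated correlation). Of pericyte and smooth muscle genes, 9 of 21 fell and 3 rose (10 and 4 adjusted over the list alone, camera adjusted p = 0.0222, adjusted p = 0.194 with an estimated correlation).

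Of photoreceptor genes, 26 of 30 fell and 0 rose (27 and 0 adjusted over the list alone, camera adjusted p = 4.25e-16, adjusted p = 0.0554 with an estimated correlation). Of inner retina genes, 16 of 37 fell and 3 rose (17 and 4 adjusted over the list alone, camera adjusted p = 0.00164, adjusted p = 0.194 with an estimated correlation). Of Müller glia genes, 7 of 22 fell and 3 rose (7 and 3 adjusted over the list alone, camera adjusted p = 0.0126, adjusted p = 0.194 with an estimated correlation). Of glycolysis and hypoxia genes, 14 of 41 fell and 1 rose (15 and 3 adjusted over the list alone, camera adjusted p = 0.0332, adjusted p = 0.323 with an estimated correlation). Of erythrocyte genes, 4 of 12 fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.0291, adjusted p = 0.283 with an estimated correlation). Without Cancer_Low 2 the inner retina genes that fell were 9, the glycolysis genes 9 (adjusted p = 0.0574) and the erythrocyte call ended (0.0508). Glycolysis also lost its call without Cancer_High 1 or Cancer_Low 4 (0.0867 and 0.0708), and pericyte genes without Cancer_Low 4 (0.0797). No list of this comparison held with an estimated correlation.

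Sox10-high cells of cancer differed from those of pre-cancerous eyes in myelin, interferon and glycolysis genes, while SOX10 itself did not pass the test (log2 fold change -0.54 ± 0.69, adjusted p = 0.68). mag (ENSDARG00000104023), a myelin glycoprotein gene, stood at 0.154 ± 0.0785 against 189 ± 29.1 CPM (log2 fold change -10.25 ± 0.98, adjusted p = 5.00e-06). plp1b stood at 4.56 ± 5.05 against 1686 ± 245 CPM (log2 fold change -8.53 ± 0.90, adjusted p = 9.75e-06). mxa (ENSDARG00000021688), an antiviral GTPase gene, rose from 7.19 ± 1.25 to 142 ± 95.3 CPM (log2 fold change 4.31 ± 0.72, adjusted p = 0.00083). GPI (ENSDARG00000012987), an enzyme of glycolysis, rose from 37.6 ± 4.86 to 419 ± 129.7 CPM (log2 fold change 3.48 ± 0.36, adjusted p = 8.56e-06). In all, 1144 genes rose and 1220 fell, but 611 rose and 1031 fell without PreC_High 1, and 683 and 1034 without PreC_High 3. Rises outnumbered falls by DESeq2 (2096 to 1876) and without Cancer_High 4 (1180 to 1118).

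Of oligodendrocyte and myelin genes, 11 of 19 fell and 0 rose (12 and 1 adjusted over the list alone, camera adjusted p = 4.06e-14, adjusted p = 0.00526 with an estimated correlation). Of neural crest and Schwann lineage genes, 5 of 26 fell and 1 rose (6 and 3 adjusted over the list alone, camera adjusted p = 0.0175, adjusted p = 0.293 with an estimated correlation), a call that ended without PreC_High 1 (adjusted p = 0.0603). Of Müller glia genes, 11 of 22 fell and 1 rose (13 and 2 adjusted over the list alone, camera adjusted p = 1.92e-13, 0.00325 with an estimated correlation). Of photoreceptor genes, 25 of 30 fell and 0 rose (25 and 0 adjusted over the list alone, camera adjusted p = 7.94e-34, 0.00325 with an estimated correlation), and GNAT1 stood at 1.01 ± 0.438 against 95.1 ± 26.4 CPM. Carry-over of sox10-low cells was not tested here. Of inner retina genes, 10 of 37 fell and 1 rose (15 and 2 adjusted over the list alone, camera adjusted p = 2.95e-05, 0.126 with an estimated correlation). Of epithelial and keratin genes, 10 of 19 fell and 2 rose (11 and 2 adjusted over the list alone, camera adjusted p = 3.21e-07, 0.106 with an estimated correlation). Of synapse genes, 5 of 33 fell and 0 rose (6 and 0 adjusted over the list alone, camera adjusted p = 0.0162, adjusted p = 0.166 with an estimated correlation). The synapse call ended without Cancer_High 2 (adjusted p = 0.0769), and 3 fell without PreC_High 3 or Cancer_High 3 and 2 without Cancer_High 1.

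Of interferon response genes, 21 of 28 rose and 0 fell (28 and 0 adjusted over the list alone, camera adjusted p = 2.06e-14, 0.0975 with an estimated correlation). Of antigen presentation genes, 11 of 19 rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 1.24e-07, 0.0975 with an estimated correlation). stat2 (ENSDARG00000031647), which carries the interferon signal to the nucleus, rose from 60.4 ± 13.6 to 364 ± 137 CPM (log2 fold change 2.59 ± 0.41, adjusted p = 0.000477). PSMB8 (ENSDARG00000001303) rose from 66.4 ± 7.95 to 397 ± 148 CPM (log2 fold change 2.58 ± 0.39, adjusted p = 0.000368), and the class I gene mhc1uba (ENSDARG00000075963) from 6.57 ± 2.61 to 43.2 ± 3.73 CPM (log2 fold change 2.72 ± 0.37, adjusted p = 0.000133). Of macrophage and microglia genes, 14 of 28 rose and 1 fell (20 and 2 adjusted over the list alone, camera adjusted p = 6.89e-05, 0.434 with an estimated correlation). Of neutrophil genes, 4 of 16 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.000949, 0.357 with an estimated correlation). SPI1 stood at 11.6 ± 2.63 against 3.42 ± 0.53 CPM. Macrophage rises were 4 without PreC_High 1 and 8 without PreC_High 2, and neutrophil rises 2 without Cancer_High 1 or 2. Neither list passed in the interaction, so carried-over sox10-low cells stay open. Of glycolysis and hypoxia genes, 19 of 41 rose and 2 fell (25 and 2 adjusted over the list alone, camera adjusted p = 1.32e-07, 0.0391 with an estimated correlation). Pyruvate kinase, PKM (ENSDARG00000099730), stood at 542 ± 199 against 101 ± 18.4 CPM (log2 fold change 2.43 ± 0.33, adjusted p = 0.000124). Cell cycle genes did not pass (0 of 39 rose and 0 fell, 0 and 0 adjusted over the list alone, camera adjusted p = 0.781). Inflammatory genes did not either (5 of 34 rose and 2 fell, 10 and 3 adjusted over the list alone, camera adjusted p = 0.0566), except with RLE scaling (adjusted p = 0.0471) and without PreC_High 1, PreC_High 2 or Cancer_High 3 (0.0402, 0.0499 and 0.0165). Fibroblast genes passed only without PreC_High 2 or Cancer_High 4 (0.0379 and 0.0395). The total of 2364 genes was 3972 by DESeq2 and 1388 with only these groups in the fit.

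The difference between sox10-high and sox10-low cells itself differed between cancer and pre-cancerous eyes for 792 genes, 550 with a higher and 242 with a lower value in cancer. The former were 265, 310 and 356 without PreC_Low 1, PreC_Low 2 or Cancer_Low 1, and the latter 131, 133, 160, 158 and 427 without these, PreC_High 3 or Cancer_Low 4. cd59a (ENSDARG00000090615), a complement inhibitor found in myelin, changed from a log2 difference of 5.12 in pre-cancerous eyes to -1.17 in cancer (interaction -6.28 ± 0.77, adjusted p = 0.00117). The myelin tight junction gene cldnk (ENSDARG00000042357) went from 4.54 to -1.40 (interaction -5.94 ± 1.12, adjusted p = 0.00833), and the enolase gene ENO1 (ENSDARG00000013750) from -4.42 to 0.14 (interaction 4.56 ± 0.67, adjusted p = 0.00172). The interaction of SOX10 did not pass (log2 fold change -3.46 ± 1.01, adjusted p = 0.0686), except without Cancer_Low 2 (0.0192).

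Of oligodendrocyte and myelin genes, 4 of 19 fell and 0 rose (7 and 0 adjusted over the list alone, camera adjusted p = 5.14e-08, adjusted p = 0.11 with an estimated correlation). Of fibroblast and extracellular matrix genes, 2 of 37 fell and 0 rose (4 and 1 adjusted over the list alone, camera adjusted p = 0.00411, adjusted p = 0.624 with an estimated correlation), with MMP14 (ENSDARG00000008388) going from 2.33 to -1.04. TFEC (ENSDARG00000098745), of the pigment cell lists, had an interaction of -2.94 ± 0.56 (adjusted p = 0.00833). Of photoreceptor genes, 4 of 30 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 8.48e-06, adjusted p = 0.412 with an estimated correlation). Of synapse genes, 2 of 33 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.000852, adjusted p = 0.15 with an estimated correlation). Of inner retina genes, 7 of 37 rose and 0 fell (9 and 6 adjusted over the list alone, camera adjusted p = 0.00988, adjusted p = 0.547 with an estimated correlation). With tissue as a block 0 inner retina genes rose and 2 fell, and glycolysis and hypoxia genes (4 of 41 rose and 0 fell, 8 and 0 adjusted over the list alone, camera adjusted p = 0.0319, adjusted p = 0.547 with an estimated correlation) lost their call (adjusted p = 0.0804). Endothelial genes (0 of 22 rose and 0 fell, 0 and 0 adjusted over the list alone, camera adjusted p = 0.0618) gained a call with the block (adjusted p = 0.0445), with RLE scaling (0.0457) and without PreC_High 3, PreC_Low 1, Cancer_High 3 or Cancer_Low 1 (highest 0.0329). No list held here with an estimated correlation, the lowest adjusted p being 0.11.

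The other lists with an interaction were neural crest (adjusted p = 0.00988), epithelial (0.015), cell cycle (0.000399), homologous recombination (0.0237), inflammatory (0.00679), iridophore (0.0199) and dissociation and immediate early genes (0.0199), each with a lower value in cancer by camera. Members called lower were 2 of 26 neural crest, 2 of 19 iridophore and 1 of 34 inflammatory genes. No cell cycle, homologous recombination or dissociation gene was called, and the 1 epithelial call, krt4 (ENSDARG00000017624), was higher (interaction 3.19 ± 0.85, adjusted p = 0.0490) but lost its call in 11 of 14 fits without 1 library and with tissue as a block (0.121). Fry called 5 of the 13 lists and none of these 7. Of the 13 lists, 9 lost their call in some fit without 1 library: without PreC_Low 3, neural crest and fibroblast (0.156 each), epithelial (0.273), inflammatory, iridophore and glycolysis (0.0659 each) and dissociation genes (0.390), and without PreC_Low 1, cell cycle (0.0546) and homologous recombination genes (0.273). The count of 792 was 415 with tissue as a block (206 higher, 209 lower), 475 with only these 4 groups in the fit, 2169 by DESeq2 and 1304 by limma voom.

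**Figure D4:**
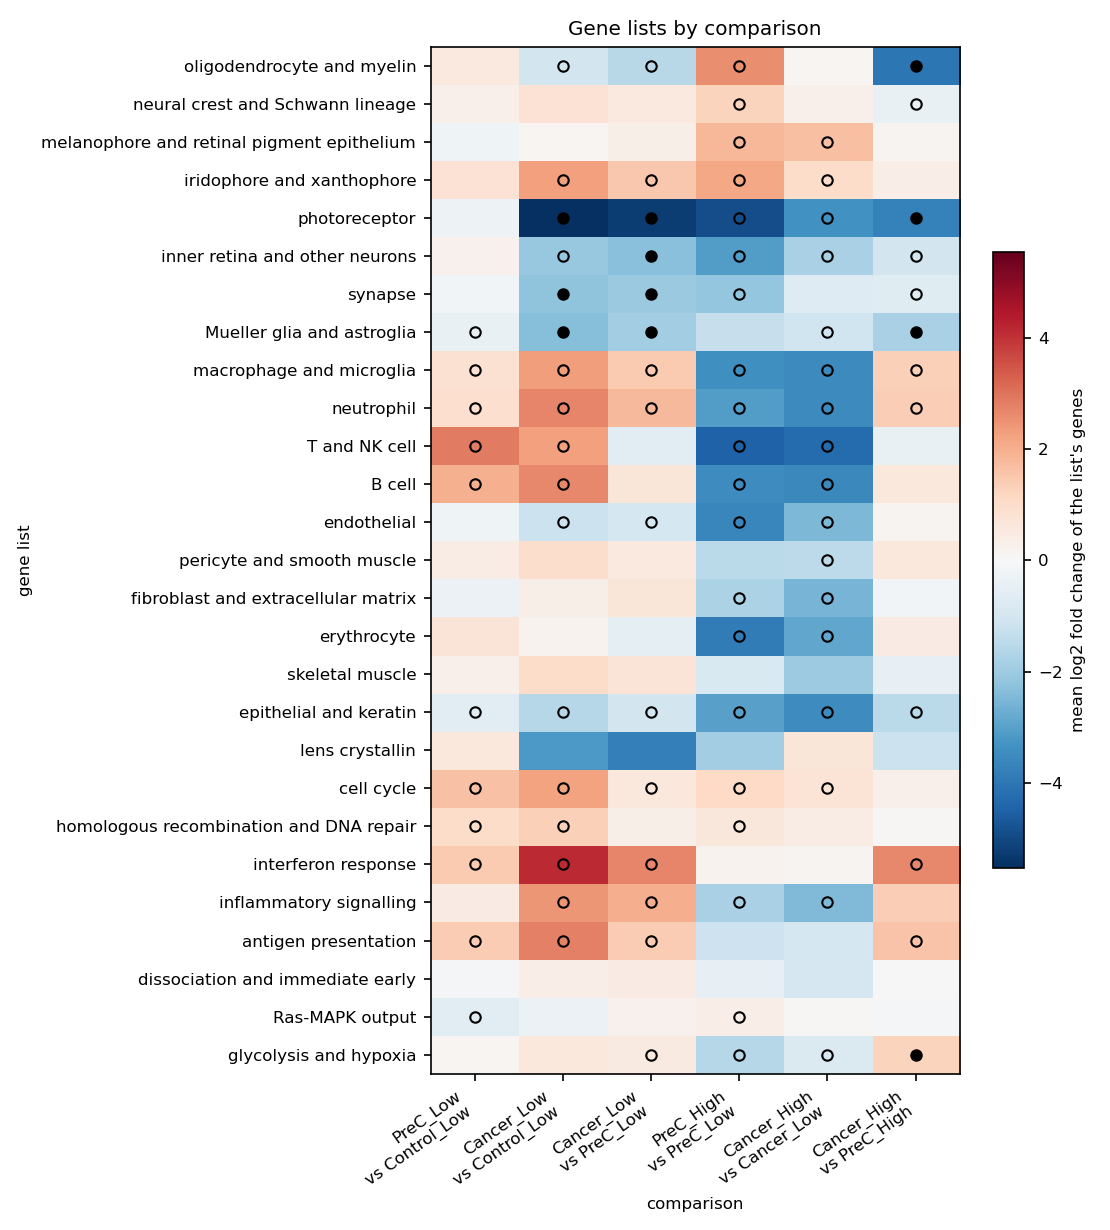
Colour gives the mean log2 fold change of the members of each of 27 lists in the 6 comparisons of groups. Open circles mark a camera adjusted p under 0.05 and filled circles those that hold with an estimated correlation, 3, 4 and 4 lists in the comparisons of Cancer_Low with Control_Low, of Cancer_Low with PreC_Low and of Cancer_High with PreC_High.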

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

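Tests chosen after the result was seen are those of carried-over sox10-high cells, of thymus tissue, of the library index, of carried-over immune cells, of the library series, of PreC_Low 3 alone and of other splits of the samples.

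Of 68 group values tested for a library far from the other 3, 5 stood out, where chance gives about 1 in 20. These are SOX10 in Cancer_Low 4 (417.7 CPM against 16.04 to 69.1), the dissociation and immediate early list in Cancer_Low 4 (mean log2 CPM 6.17 against 7.65 to 7.78), the B cell list in Cancer_High 2 (1.42 against -0.08 to 0.17), the endothelial list in Cancer_High 3 (-1.42 against -0.70 to -0.56) and the interferon list in Cancer_High 4 (5.35 against 6.96 to 7.02).

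The High against Low difference differed between Cancer and PreC, by the interaction term, for 792 genes. Of these, mstnb (ENSDARG00000069133), proca1 (ENSDARG00000069823), pdha1b (ENSDARG00000010555) and BOK (ENSDARG00000008807) had the largest positive log2 values under the naming rule, 8.26, 7.23, 6.52 and 5.95, and cd59a, cldnk, MFSD6 (ENSDARG00000054583) and PLCL1 (ENSDARG00000067676) the largest negative, -6.28, -5.94, -5.47 and -5.33. The call of mstnb ended without PreC_High 1 or PreC_High 3 (highest adjusted p = 0.0616) and of BOK without PreC_High 1, PreC_Low 1, PreC_Low 2 or Cancer_Low 1 (highest 0.0630). With tissue as a block, mstnb (4.66, adjusted p = 0.123), proca1 (5.26, 0.0852) and BOK (5.41, 0.0548) lost their calls. Without Cancer_High 2, mstnb stood at 3.78 and proca1 at 4.72. The lists were myelin (adjusted p = 5.14e-08), neural crest (0.00988), iridophore (0.0199), photoreceptor (8.48e-06), inner retina (0.00988), synapse (0.000852), fibroblast (0.00411), epithelial (0.0150), cell cycle (0.000399), homologous recombination (0.0237), inflammatory (0.00679), dissociation and immediate early (0.0199) and glycolysis (0.0319). With an estimated correlation none held (lowest adjusted p = 0.110).

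Cell cycle genes were high in PreC_Low 3, at a mean log2 CPM of 4.92 against 2.63 and 2.84 in PreC_Low 1 and 2. Carried-over sox10-high cells are argued against by SOX10 at 9.76 CPM in that library, below both others, and an effect of library index 6 to 9 by a cell cycle level of at most 2.63 in the other Low libraries of that range. Thymus tissue in the dissected sample stays open. RAG1 (1110 CPM), RAG2 (1020 CPM) and cd8b (274.2 CPM), chosen after their values were seen, were high there. Of 17 further thymus genes 9 were highest in PreC_Low 3 among the 10 Low libraries, but 5 of these are on the T and NK cell list, already seen high. Of the 11 outside it 4 were (36.4%, binomial p = 0.0185), all of them genes of T cells (cd247, THEMIS, bcl11ba and IKZF1). Genes of thymic epithelium were not higher: foxn1 stood at 0.093 CPM, psmb11b at 0 and ccl25b at 135.5, against at most 1.58, 0.82 and 291.7 in the other Low libraries. Pituitary tissue stays open too, with 2 of 9 further genes (22.2%, binomial p = 0.225) highest there, although gh1 (140.8 CPM), CGA (109.5), TSHB (148.2) and POMC (115.8), also chosen after their values were seen, were at most 1.09 CPM in the other Low libraries. An expansion of immature T cells in mutant fish also stays open, as untested.

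Interferon genes were high in both cell fractions of cancer. Immune cells carried over into Cancer_High are argued against as the whole source, since the median log2 fold change of the interferon list between Cancer_High and Cancer_Low was 0.19, against -3.78 (SD 1.07) for macrophage genes. Library series cannot be told apart from stage, because 0 Cancer libraries have an index from 1 to 9. A response in the cancer cells themselves, and the greater age of the fish, stay open as untested.

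The genes called between PreC_Low and Control_Low may in part reflect strain variants against the reference. Of the 250, 155 (62%) lay in all 14 mutant libraries, of both fractions and stages, on one side of all 3 controls, against 8.69% of genes not called. Only 74 of the 155 differed by under 2-fold between PreC_High and PreC_Low. All controls are Low libraries, so for the rest the sort itself can set the High libraries apart from them. Among genes whose PreC_Low and Control_Low libraries do not overlap, which chance alone gives for 10%, the shares were 62.5% of 248 called and 37.2% of 5383 others. An effect of the mutations in all cells would give the same values and stays open. Thymus or pituitary tissue in PreC_Low 3 is argued against as the whole cause, since 74 of the 250 were called again, in the same direction, without that library. A part stays open: the calls were 83 in all there, though 50 to 83 without 1 control library.

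Chance is argued against, uncorrected for several tests, where only the real split of 35 had as many calls. These are Cancer_Low with Control_Low (7631, highest other 4096), Cancer_Low with PreC_Low (4440, 2687), Cancer_High with PreC_High (2364, 1017) and the interaction (792, 6). PreC_Low with Control_Low (250, 0) and PreC_High with PreC_Low (7288, 15) have 10 splits, too few for a share under 0.05. Cancer_High with Cancer_Low (6613) is paired by tissue, and the 8 splits that part all 4 pairs are also too few. Of the splits that part as many tissue pairs, the 3 others of PreC_High with PreC_Low gave at most 15 calls and the 7 others of Cancer_High with Cancer_Low 0. The highest split of the latter that parts fewer pairs, 1905, sets Cancer_Low 4 among the Cancer_High libraries.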

How the results depend on the processing

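The filter by mean count, the index block, the joint removal of PreC_Low 3 and Cancer_Low 4 and the list fits without a library or with a block were chosen after the data were seen. No named gene or called list reversed under any alternative run: named genes were on the same side of the threshold in 10731 checks, gained a call in 134 and lost one in 639, and called lists kept their call in 1082 checks and lost it in 188. Lists without a call gained one in 42 of 853 checks, without 1 library, with RLE factors or with the replicate block. Of these, the ones not given with the results are of lens genes (lowest adjusted p = 0.0210, Cancer_Low with PreC_Low without PreC_Low 3), antigen presentation genes (0.0371, PreC_High with PreC_Low without PreC_Low 1), skeletal muscle genes (0.0317, Cancer_High with Cancer_Low without Cancer_Low 2) and, for the interaction, macrophage genes without Cancer_Low 4 (0.0251) and interferon genes without PreC_Low 2 (0.0456).

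DESeq2 called 1497 genes for PreC_Low with Control_Low, 3972 for Cancer_High with PreC_High and 2169 for the interaction, and 1180 shared against Control_Low. Limma voom called 783, 1304 for the interaction, and 672 shared. Only the groups compared gave 866 for PreC_Low with Control_Low, 1388 for Cancer_High with PreC_High and 475 for the interaction. The replicate block gave 1054, 957 and 415, but pairs tissues only for the last; in the first 2 it rests on title numbers alone. The index block gave 399 for PreC_Low with Control_Low. Without PreC_Low 3 and Cancer_Low 4 there were 162 for PreC_Low with Control_Low, 1388 for the interaction and 147 shared. With an estimated correlation 11 of the 105 called lists held, and fry, which tests another question, called 84 of them: 2 of 11 for PreC_Low with Control_Low, 5 of 13 for the interaction, 13 of 15 for Cancer_Low with PreC_Low, 19 of 20 for PreC_High with PreC_Low, 16 of 17 for Cancer_High with Cancer_Low, and all of the others. It called 10 lists that camera did not. Leaving out each library in turn gave 50 to 405 for PreC_Low with Control_Low, 5553 to 7480 for Cancer_Low with Control_Low, 2859 to 5079 for Cancer_Low with PreC_Low, 5540 to 7999 for PreC_High with PreC_Low, 4715 to 8091 for Cancer_High with Cancer_Low, 1642 to 2298 for Cancer_High with PreC_High, 396 to 1218 for the interaction and 48 to 361 shared. Fewer samples are in the left-out fits and in those of only the compared groups. The cause of the other differences was not tested.

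RLE factors, no filter and the stricter filters left the totals of called and shared genes within 1.5 times. Of the counts by direction, the 181 rises in PreC_Low against Control_Low became 111 with RLE factors and 107 with the mean count filter, and the 167 shared rises 107 and 103. Where totals stayed within 1.5 times, the 2161 genes higher in PreC_High than in PreC_Low were 3371 by DESeq2, 3707 by limma voom, 3601 with the replicate block and 3605 without PreC_Low 3 and Cancer_Low 4, and the 5127 lower 3357 with the index block. The 1852 rises in Cancer_Low against PreC_Low were 3225 by DESeq2, and the 2439 genes higher in Cancer_High than in Cancer_Low 4075 without PreC_Low 3 and Cancer_Low 4. Libraries 1 to 9 hold fewer IDs with 3 to 20 counts (632 to 2344) than the Cancer libraries (3361 to 4295) at totals that overlap. The cause of this and of their even values was not tested.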

Other observations

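Of the lists not described above, dissociation and immediate early genes passed in no comparison of groups with all libraries (without Cancer_Low 4, adjusted p = 0.00304 for Cancer_Low with PreC_Low and 0.00411 for Cancer_High with Cancer_Low; without PreC_Low 2 or Cancer_High 4, at most 0.0478), yet single members moved. In cancer, the transcription factor genes EGR3 (ENSDARG00000089156) and NR4A1 (ENSDARG00000000796), induced early after stimulation, were lower in sox10-high cells (log2 fold change -5.19 ± 0.73, adjusted p = 6.99e-05 and log2 fold change -3.61 ± 0.55, adjusted p = 0.000131).

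Cancer_Low 4 lay toward its own High library. For 228 genes far higher in the Cancer_High mean than in that of the other 3 Low libraries, its level stood at a median of 50.1% of the way from these to its own High library (quartiles 34.8 to 70.6%). Cancer_Low 1, 2 and 3 were each set against the other 2 of the 3, leaving Cancer_Low 4, the library in question, out of the reference. With 291, 181 and 231 such genes, their medians were 7.77, -6.82 and 0.456%. For 373 genes far lower in Cancer_High, Cancer_Low 4 stood at a median of 73.7% below the other Low libraries. In Cancer_Low 1, 2 and 3 this was 23.8, -1.95 and 37.2%, with 384, 325 and 390 genes. RAG1 and RAG2, named after their values were seen, stood at 29.7 and 36.5 CPM in PreC_High 3, of the same tissue as PreC_Low 3, and at most 0.353 CPM in PreC_High 1 and 2.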
